A study of Homo sapiens with 2 samples.

How the data were processed

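Total RNA of MCF10A cells was labelled with Cy3 and hybridised to 1 array per group, per the labels' protocols. The groups were control siRNA (1 array) and KRT81 siRNA (1 array), taken from the labels. The description of the latter sample mentions a plant extract, which its title, source name and treatment label do not. The siRNA sequences, dose and time after transfection are not given in the sources used here. Both arrays lay on 1 slide and in 1 scan, per the file headers, so slide and scan do not differ between the groups.

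The deposited scanner files hold spot intensity values on a linear scale, extracted with Agilent Feature Extraction for array design 039494, per the file headers, with probe coordinates on hg19. The software version is 10.7.3.1 per the file headers and 10.10 per the submitters' processing notes. The processed intensity is background-subtracted and not normalized between arrays. The authors' deposited value table holds the same processed intensity on a linear scale, since all 49697 probes printed once were equal to it within 0.0001 on the log2 scale. Its column medians were 22.6 for control siRNA and 25.3 for KRT81 siRNA, and neither scale, centring nor direction stayed unknown.

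From these, log2 of the processed signal was taken, and the 75th percentile of each array over probes that are not controls was subtracted. That percentile was 331 on the control siRNA array and 332 on the KRT81 siRNA array. Control spots and 666 spots marked as non-uniform or outliers on either array were left out, and no spot was saturated. Spots of one probe were averaged. Of 50599 probes, 22429 were well above background on both arrays, 1099 on the control siRNA array only and 2401 on the KRT81 siRNA array only. A gene's value was the mean over its probes well above background on both arrays, and 12996 of the 17035 genes were measured by 1 probe. Among the 4039 genes with more probes, the median range between probes was 0.26, 278 genes had probes more than 1 apart, and 41 had probes of opposite sign beyond 0.5. The number of arrays limits the precision.

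Gene names were updated through a RefSeq gene table (assembly GRCh38.p14, names only) for 28174 probes by accession, 2618 by symbol and 620 by synonym, and 19187 probes kept the name in the files. Of 17767 measured probes that list RefSeq transcripts, 770 list transcripts of several genes. Exon and untranslated region positions of the probes were not analysed here.

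No statistical test was made, since 1 array per group leaves no estimate of the spread. Genes were counted by size, at 2-fold. For each gene list, the median log2 ratio was placed among 10000 random lists of the same size matched on mean log2 signal in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5 with at least 5 genes measured. Relative medians have the median of all genes subtracted. For a gene well above background on 1 array only, the bound set its level there against the higher of the dim probe's own level and the lowest signal among probes well above background on the other array.

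The rule for named genes, the 38 gene lists and a first set of other settings were fixed before the data were examined. The rule took KRT81 and the type II hair keratins, and the 14 highest and 14 lowest genes with a usual symbol, a signal above the median and all probes in one direction. It also took up to 5 genes measured on each array only, and the 2 to 4 most different and the best known members of each list, some of which are not reported here. Y-linked genes and XIST are not reported here. Their exclusion was decided after values were seen, when a first ranking of genes measured on 1 array only held a Y-linked gene, and OR8D2 took its place.

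These settings were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, scaling to the median, the authors' value table, the brightest probe per gene, no filter on dim probes, bright probes only, removal of the trend with signal, random lists matched on size alone, and thresholds of 1.5-fold and 3-fold. Scaling to spike-ins, removal of the trend with probe GC content, removal of both trends and 6 further gene lists were added after the data were seen. Of the spike-in probes, 8 were above background, with a median log2 ratio of 0.13 (0.10 to 0.22) after percentile scaling.

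The procedure was tested on simulated data for the comparison of KRT81 siRNA with control siRNA over 17035 genes, with a noise SD of 0.3 per spot that was set by choice and not estimated. At log2 shifts of 2 and -2, 50 of 50 genes each passed 2-fold. At 1.3, 40 of 50 passed, and at -1.3, 35 of 50. Of 16805 genes with no shift, 248 passed 2-fold. Of 40 random lists with no shift, 2 stood apart, a number largely set by the cutoffs because the simulated noise was independent between genes. It says nothing about lists of co-regulated genes. The counts hold for the chosen noise and not for these arrays, where the median SD of a log2 ratio between spots was 0.07.

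Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 (for normexp and quantile normalization), were used.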

Results

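RNA from MCF10A cells, an immortalised and non-tumorigenic human mammary epithelial line, was profiled on 2 one-colour expression arrays. According to the labels, 1 array held cells transfected with a control siRNA and 1 held cells transfected with an siRNA against KRT81, a type II keratin known from the hair shaft. The question was which transcripts differ when KRT81 is repressed. Of 58717 gene-directed spots, 50.1% were well above background on the control siRNA array and 52.5% on the KRT81 siRNA array. Values are log2 ratios of the KRT81 siRNA array over the control siRNA array after each array was scaled to its own 75th percentile. With 1 array per group no difference has a replicate check, no test was possible, and all directions below describe these 2 arrays. The free-text description of the KRT81 siRNA sample speaks of a plant extract, whereas its title, source name and treatment label name the siRNA, which was taken as its group.

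KRT81 was lower on the KRT81 siRNA array. Its probe, on the minus strand of chromosome 12 at 52679699 to 52679758 (hg19), had a processed signal of 222086 with the control siRNA and 37222 with the KRT81 siRNA, a 5.97-fold lower level (log2 ratio -2.58). KRT83, a neighbouring type II hair keratin, was lower as well. The probe listed for KRT83 alone, at 52710677 to 52710736 of the same chromosome, was 19.2-fold lower, with signals of 5563 and 291. A further KRT83 probe, at 52709702 to 52709761, also lists KRT81 and KRT85 transcripts and was 4.77-fold lower, so the level of KRT83 read from it is uncertain. KRT85 had a log2 ratio of -0.96 and KRT86 of 0.43, both from probes of low signal. KRT82 and KRT84 were not well above background on either array. Of the 11 type I hair keratins, the partners of the type II chains, only 3 were measured on both arrays, with log2 ratios of -1.20 for KRT34 and, at low signal, -0.97 for KRT39 and -0.30 for KRT31. KRT32 was well above background on the KRT81 siRNA array only.

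**Figure D1:**
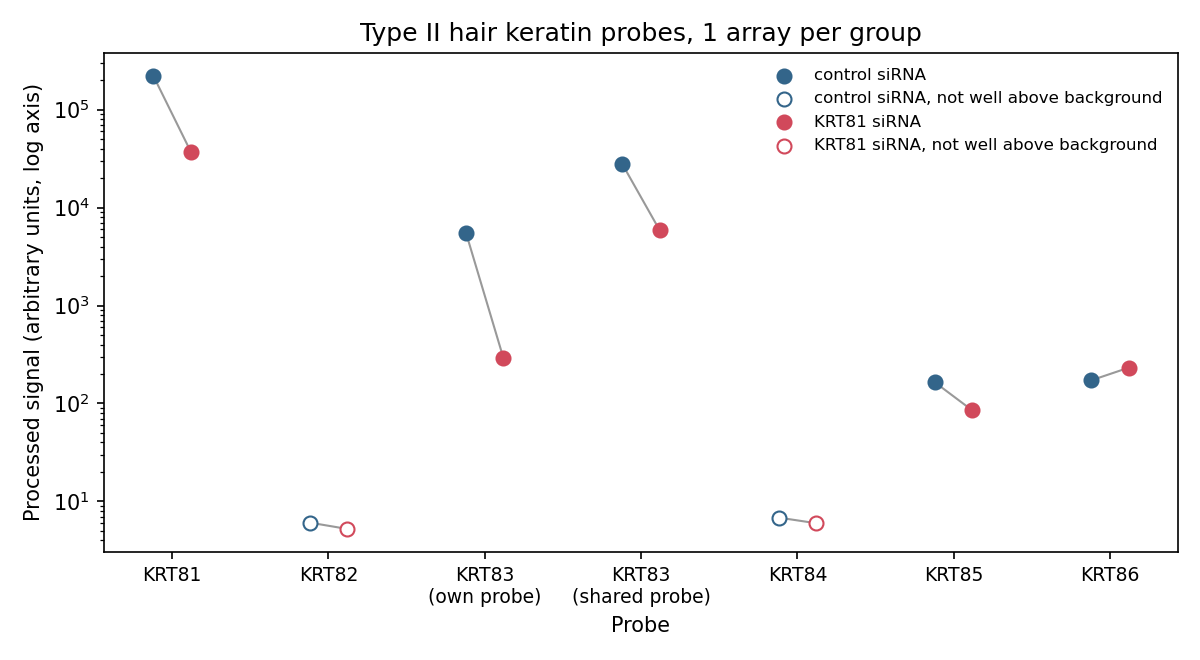
Processed signal (log axis, arbitrary units) of each type II hair keratin probe on the control siRNA and KRT81 siRNA arrays, with open circles where a probe was not well above background. KRT81 goes from 222086 to 37222 and the probe listed for KRT83 alone from 5563 to 291, while KRT86 goes from 172 to 232.

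Among genes well above background on both arrays, more were at least 2-fold lower with KRT81 siRNA than higher. Of 17035 such genes, 725 were at least 2-fold lower and 300 at least 2-fold higher. At 4-fold the numbers were 145 lower and 40 higher, and at 8-fold 43 lower and 10 higher. Across genes the log2 levels of the arrays correlated with r = 0.977, genes not being independent replicates. The log2 ratio of probes printed 10 times had a median SD of 0.07 between spots, which covers spot-to-spot error within an array pair and nothing else. The median gene had a log2 ratio of 0.08, and the share of lower genes among the 2-fold different ones was 70.7%. Scaling to the spike-in probes moved that median to -0.05 and the share to 82.1%, and median scaling gave a share of 66.5%. Without a filter on dim probes, 2045 genes were lower and 2047 higher among 36400, so the lean to lower levels was absent there.

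**Figure D2:**
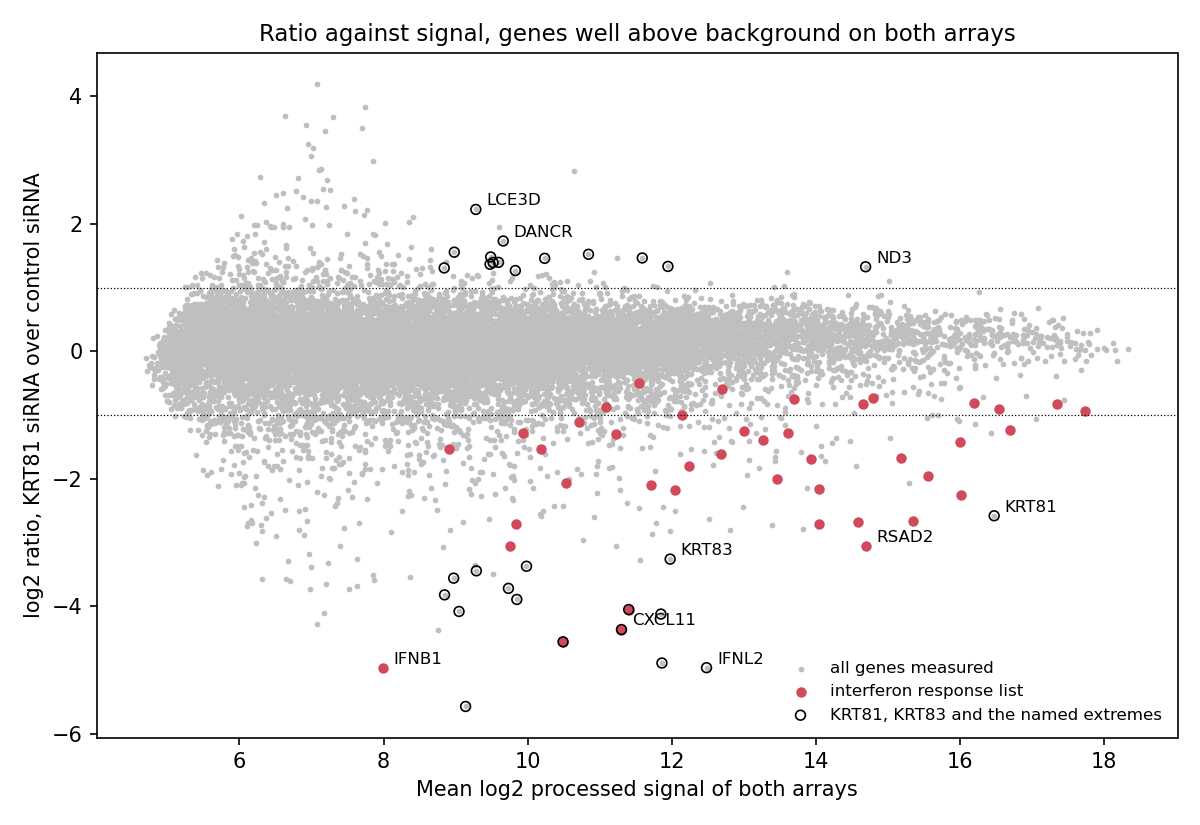
Log2 ratio of KRT81 siRNA over control siRNA against the mean log2 processed signal of both arrays, for each of the 17035 genes measured (grey), the interferon response list (red) and the genes named as extremes (open circles); dotted lines mark 2-fold. The 42 interferon response genes all lie below the median of all genes, 0.08.

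Among genes with a usual symbol and a signal above the median, the 14 lowest included interferon and chemokine genes. The type III interferon genes IFNL3, IFNL2 and IFNL1 were 47.4-fold, 31.1-fold and 23.5-fold lower, although IFNL2 and IFNL3 are near-identical copies, so that their separate values are uncertain. With normexp and quantile normalization the log2 ratio of IFNL3 was -4.69 in place of -5.57, behind the -4.89 of IFNL2. Of the chemokines that attract T cells, CXCL11 was 20.6-fold, CCL5 17.4-fold and CXCL10 16.5-fold lower, the last by both of its probes. PLAAT2, a phospholipid acyltransferase, was 29.6-fold lower. The interferon-inducible GTPases GBP4 and GBP5 were 13.1-fold and 11.8-fold lower, and TNFSF13B, the B cell activating factor BAFF, was 10.9-fold lower. The rest of the 14 lowest genes were the short-chain dehydrogenase DHRS2 (log2 ratio -4.08), NEURL3 (-3.89), CSAG1 (-3.82) and SLC15A3 (-3.37), a lysosomal peptide and histidine transporter. With normexp and quantile normalization DHRS2 had -3.45 and CSAG1 -3.20.

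Under the same conditions on symbol and signal, the genes at the upper end differed by less, while larger positive ratios lay among dimmer or otherwise named genes. LCE3D, a late cornified envelope protein, was 4.67-fold higher and led the list. The long noncoding RNA DANCR was 3.32-fold higher, the platelet chemokine PF4 2.94-fold and CMTM4 2.87-fold. CD14, a lipopolysaccharide co-receptor, was 2.79-fold higher, ARHGDIB 2.76-fold and CSF1R, the receptor for macrophage colony-stimulating factor, 2.75-fold. The bradykinin receptor genes BDKRB1 and BDKRB2, neighbours on chromosome 14, were 2.63-fold and 2.62-fold higher. The remainder of the 14 highest comprised the complement inhibitor CD59 (log2 ratio 1.36), the small nucleolar RNA host gene SNHG9 (1.33), the mitochondrial complex I subunit ND3 (1.33), the exchange factor NGEF (1.31) and the homeobox gene HOXA10 (1.27).

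Among the lists fixed beforehand with at least 5 genes measured, interferon response genes had the lowest median. All 42 members were measured, all 42 lay below the median of all genes, and 31 were at least 2-fold lower. The median of the list relative to all genes was -1.65, below all 10000 random lists matched on signal. IFNB1, which encodes interferon beta, was 31.2-fold lower, although it did not meet the conditions on symbol, signal and probes set for the 14 lowest genes. The antiviral effectors RSAD2 and HERC5, the latter a ligase for ISG15, had log2 ratios of -3.06 and -3.05. MX1, a GTPase that restricts influenza virus, had -1.67 and the ubiquitin-like modifier ISG15 -0.93. Markers of immune cells did not follow. Of 16 such markers 8 were measured, with a relative median of 0.24 at percentile 93.5, where CD14 and CSF1R were higher, PTPRC had 0.29 and CD68 -1.82.

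Inflammatory and immediate early genes were lower in part. Of 30 measured NF-kB targets and cytokines, 10 were at least 2-fold lower and none was 2-fold higher, with a relative median of -0.46 below all 10000 random lists. After CCL5, examples were the cytokine IL6 (log2 ratio -2.23), the interleukin 1 antagonist IL1RN (-1.66) and the prostaglandin synthase PTGS2 (-1.60). The neutrophil chemokines CXCL8 and CXCL1 had -0.15 and 0.42, and the growth factor CSF2 had 0.67. The 28 measured immediate early genes and EGF receptor ligands had a relative median of -0.64, also below all random lists, with 3 at least 2-fold lower. These were the EGF receptor ligand BTC (-1.28), the AP-1 subunit FOSB (-1.02) and the MAP kinase phosphatase DUSP1 (-1.02). MYC had -0.78.

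Genes of epidermal differentiation were lower, apart from a few. Among 24 measured, 9 were at least 2-fold lower and none was 2-fold higher, and the relative median of -0.97 lay below all random lists. TGM1, the transglutaminase that cross-links the cornified envelope, had a log2 ratio of -2.37, CRCT1 -2.24 and SBSN -1.92. KRT80 had 0.82 and IVL, the envelope precursor involucrin, 0.24. LCE3D, 4.67-fold higher, is not in this list. Basal epithelial keratins and markers had a relative median of -0.44 over 19 genes (percentile 0.01), with KRT6B at -2.06, the p53 family regulator TP63 at -0.73, KRT14 at -0.55 and KRT5 at -0.50. Only KRT6B passed 2-fold, and some basal markers were higher, such as MYLK at 0.53 and ITGB4 at 0.30. Luminal mammary markers did not stand apart (14 genes, relative median -0.13, percentile 7.85) except with bright probes only (percentile 1.98). Among them KRT18 had 0.68 and KRT8 0.54, against -0.75 for MUC1 and -0.44 for GATA3.

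Genes of tight junctions and desmosomes were slightly lower, while integrins, laminins and hemidesmosome genes did not stand apart (21 genes, relative median 0.02, percentile 35.5). The relative median was -0.31 for 16 genes of the tight junction list (percentile 0.41), with the barrier proteins CLDN1 at -1.17 and OCLN at -0.82. That list also holds the splicing factors ESRP1 (-0.45) and ESRP2 (0.49). For 17 desmosome and adherens junction genes it was -0.21 (percentile 1.90), none of them 2-fold different, with the desmosomal cadherin DSC3 at -0.60 and desmoplakin, DSP, at -0.51. E-cadherin, CDH1, had 0.03. The list of extracellular proteases, which also holds the TIMP protease inhibitors and BSG, had a relative median of -0.16 over 28 genes (percentile 1.99). Of these genes, 4 were at least 2-fold lower. The collagenase MMP13 had -2.69 and the matrilysin MMP7 -1.18, against 0.01 for the collagenase MMP1. Without matching on signal, the desmosome and protease lists no longer stood apart, nor did the tight junction list with bright probes only (percentile 2.55).

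Genes of DNA replication, mitosis and ribosomes were higher by small amounts, while replication-dependent histone genes did not stand apart (26 genes, relative median 0.11, percentile 81.7). The relative medians of 34 DNA replication genes, 0.43, and of 40 mitosis genes, 0.35, lay above all 10000 random lists. The S phase transcription factor E2F1 was 2.15-fold higher, cyclin E1, CCNE1, 2.03-fold and the replicative helicase subunit MCM6 1.99-fold. Of the mitosis genes, the transcription factor MYBL2 was 2.29-fold higher and the kinase AURKB 1.99-fold, while the spindle checkpoint kinase TTK had a log2 ratio of -0.81 and the cytokinesis protein ANLN -0.72. Ribosome biogenesis and MYC target genes had a relative median of 0.28 over 30 genes (percentile 99.96), led by ODC1, the first enzyme of polyamine synthesis, with 1.24. The 44 cytosolic ribosomal protein genes had a relative median of 0.22 (percentile 99.84). None of them was 2-fold different, and RPLP0 had 0.66.

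Some metabolic, stress and signalling lists also stood apart, but oxidative phosphorylation (percentile 63.5), fatty acid synthesis (80.0), the unfolded protein response (12.7) and heat shock proteins (7.48) did not. Glycolysis and hypoxia genes had a relative median of -0.22 over 34 genes (percentile 0.06), with the carbonic anhydrase CA9 at -2.61 and the vasoactive peptide ADM at -1.16, against 0.93 for ANGPTL4. NRF2 targets had a relative median of 0.21 over 28 genes (percentile 99.58), with AKR1B10 at 1.33 and AKR1C1 at -1.05. The probes of AKR1B10 were of low signal and differed, with 0.63 and 2.04. Cholesterol synthesis genes had 0.21 over 24 genes (percentile 97.66), with ACAT2 at 0.80 and the sterol carrier STARD4 at -1.04. The p53 targets and cell cycle inhibitors had -0.17 over 31 genes (percentile 1.18), with the inhibitor CDKN1C at -1.80, the death receptor FAS at -1.77 and CDKN1A at 0.02. TGF-beta and BMP response genes had -0.21 over 21 genes, with BMP2 at -1.24 and, from 1 probe of low signal, TGFBR1 at 1.32. YAP and TAZ targets had -0.17 over 22 genes, with the kinase NUAK2 at -3.05 and LATS2 at -1.32. Both of these last lists were at percentile 2.31. The YAP and TAZ relative median turned to 0.00826 without a filter on dim probes, where the subtracted median of all genes moved from 0.08 to -0.09. Both of these lists lost their place apart under several settings. The p53, NRF2 and cholesterol lists each lost it under 2 or 3 settings.

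Of the 38 gene lists fixed beforehand, 35 had at least 5 genes measured and 18 stood apart, 12 low and 6 high, where 1.75 would be expected by chance for independent lists. Lists share genes and genes are co-regulated, so the percentiles describe these arrays and are not tests. The lists that did not stand apart included mesenchymal genes, with a relative median of -0.02 at percentile 36.8 and VIM at 0.49, and estrogen receptor targets, with 0.01 at percentile 51.1. Fibroblast markers, 7 of them measured, had 0.13 at percentile 73.3. Only 2 of 12 endothelial markers were measured. Commonly used reference genes had a relative median of -0.02 over 20 genes, with GAPDH at 0.16, while B2M, the light chain of class I antigen presenting molecules, had -1.05.

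**Figure D3:**
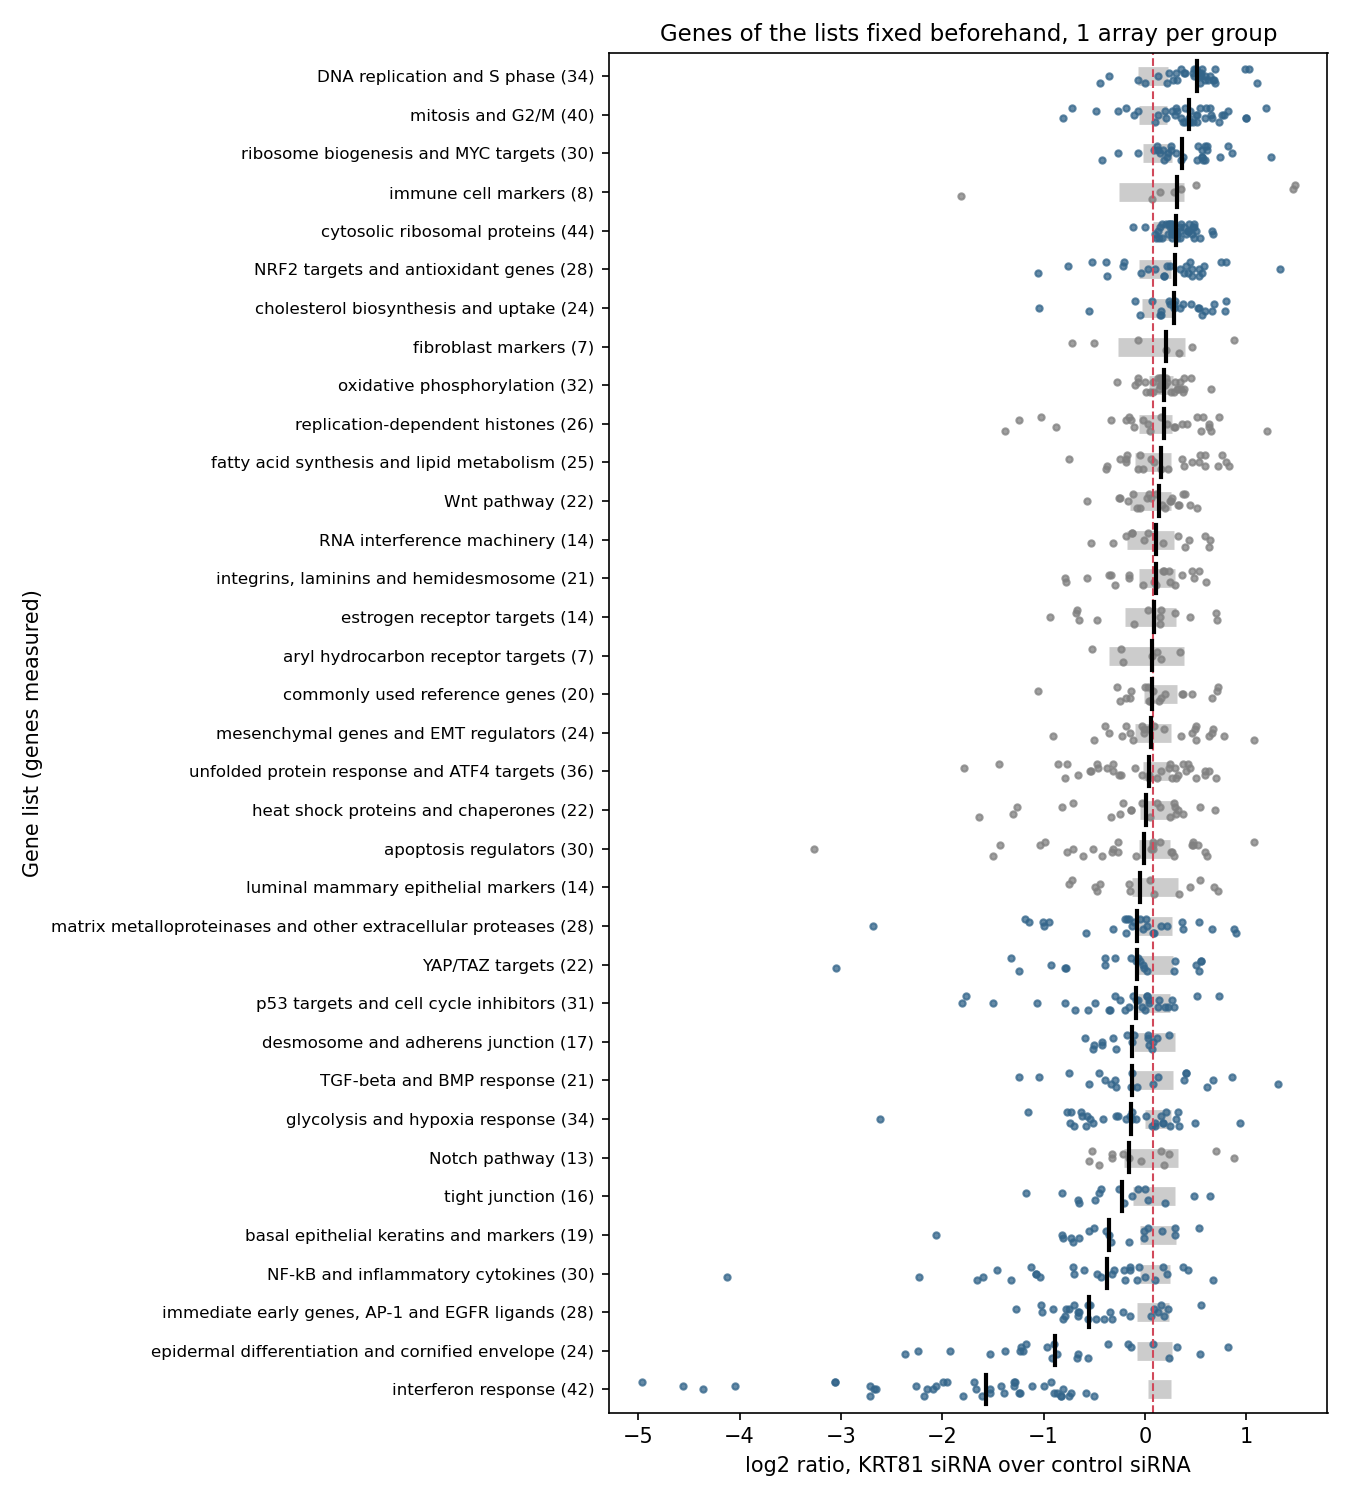
Log2 ratio of KRT81 siRNA over control siRNA for each measured gene (points, blue where the list stood apart) of the 35 lists with at least 5 genes, with list medians (black bars), the central 95% of medians of matched random lists (grey bands) and the median of all genes (dashed line, 0.08). The interferon response list lies furthest to the left, and DNA replication furthest to the right.

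Some genes were well above background on 1 array only. There were 362 such genes on the control siRNA array and 704 on the KRT81 siRNA array. A fold was bounded from the dim array, taking the higher of the lowest signal among probes well above background and the dim probe's own, and the bound was at least 2-fold for 214 and 205 of them. With control siRNA only, the defensin DEFB119 was at least 22.4-fold higher by 1 probe, its other probe not being well above background on either array, the transporter SLC22A9 at least 19.3-fold, CSAG2 at least 19.1-fold by a probe that also lists CSAG3, and the intraflagellar transport protein IFT57 at least 17.5-fold. ERVK13-1 was at least 16.9-fold higher by 1 of 3 probes, the others not being well above background on either array. With KRT81 siRNA only, the complement subunit C1QA was at least 19.9-fold higher, ZNG1F at least 17.2-fold, PRDM12 at least 15.9-fold, the meiotic recombinase DMC1 at least 15.6-fold and the olfactory receptor OR8D2 at least 15.1-fold. Isolated bright spots on dim probes printed 10 times would give about 21.0 single-spot probes with a signal above 300 on the control siRNA array and about 46.6 on the KRT81 siRNA array, against 38 and 60 found.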

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

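Spike-in scaling and the removal of the GC trend, alone or with the signal trend, were chosen after the results were seen, and the other settings before. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. The KRT81 log2 ratio of -2.58 was -2.67 with quantile normalization, -2.69 without the signal trend, -2.71 with spike-in scaling and -2.68 without both trends, and between -2.61 and -2.54 under the others. The 300 genes at least 2-fold higher and 725 at least 2-fold lower became 121 and 414 with normexp and quantile normalization, of which 121 and 411 were the same genes. Without a filter on dim probes they were 2047 and 2045, over 36400 genes instead of 17035, and with bright probes only 65 and 325 over 9400 genes. At 1.5-fold they were 1473 and 1746, and at 3-fold 71 and 261. Spike-in scaling gave 208 and 951. Quantile normalization of the processed signal without normexp gave 292 and 733, so the fall to 121 and 414 did not come with quantile normalization. It came with the normexp step (offset 50) or with its input. That input was the mean spot signal and the median background in place of the processed signal, and step and input were not separated. Apart from these, the thresholds and the number of genes, the cause was not tested. Of the 18 lists that stood apart, 10 did so under every setting: interferon response, NF-kB, epidermal differentiation, immediate early genes, basal markers, glycolysis and hypoxia, DNA replication, mitosis, ribosome biogenesis and cytosolic ribosomal proteins. The relative median of YAP and TAZ targets turned from -0.17 to 0.00826 without a filter on dim probes. The median of all genes, which is subtracted, moved there from 0.08 to -0.09, so the turn came from this reference. In 23 further combinations of list and setting a list no longer stood apart, and in 3 a list did so that had not, against 392 with no such difference. For single named genes, 82 values moved by more than their tolerance and 257 did not, and none of these turned in direction. The tolerance was the median spot SD of 0.07 or, for genes with several probes, the distance of the outer probes from their midpoint where that was larger. On the control siRNA array only 50.1% of spots were well above background, which limits what can be said of genes of low signal.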

Other observations

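All tests in this part, and the 6 gene lists that open it, were chosen after the values were seen. Genes of antigen presentation by class I molecules were lower with KRT81 siRNA. All 17 of them lay below the median of all genes, 5 were at least 2-fold lower, and the relative median of -0.90 was below all 10000 random lists. The peptidase ERAP2 had a log2 ratio of -1.74, the immunoproteasome subunit PSMB9 -1.72 and HLA-F -1.36. Of 6 measured guanylate-binding protein genes, 5 were at least 2-fold lower, with a relative median of -2.70, also below all random lists. That place was in part given in advance, since GBP4 and GBP5 were already among the 14 lowest genes when the list was added. Complement and acute phase genes had a relative median of -0.57 over 15 genes (percentile 0.01), with complement factor B, CFB, at -2.63 and C1S at -1.82, while the serum amyloid gene SAA1 had -0.06.

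A list of ELF3, KLF and other epidermal transcription factors, also drawn up after the values were seen, was lower too. All 11 lay below the median of all genes, GRHL3 only just, with a log2 ratio of 0.07 against 0.08. The relative median was -0.72 (percentile 0.04), and 5 genes were at least 2-fold lower, among them PRDM1 at -2.07 and OVOL1 at -2.03. KLF4 and KLF6 are also in the immediate early list, so those lists overlap. Host genes of small nucleolar RNAs had a relative median of 0.26 over 17 genes (percentile 98.7). Their list holds DANCR and SNHG9, already among the 14 highest genes, so its place is not independent of that ranking. The 20 tRNA synthetase genes did not stand apart (relative median 0.16, percentile 88.0), and WARS1, known to be induced by interferon, had -2.78 against 1.07 for VARS1.

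The pattern weighed first is the low level of interferon response genes. A bias with probe signal or GC content is argued against as the whole cause, since the relative median of the list was -1.69 after both trends were removed. For leukocytes in the control culture, the relative median of the immune cell markers was 0.24 (SD 1.02 over 8 markers). That was more than an SD above that of the interferon genes. Its weight is small, since MCF10A is an epithelial line and markers such as PTPRC and CD3D were of low signal. The markers also differed in direction, with CD14 at 1.48 and CD68 at -1.82. A stronger innate response to the control duplex than to the KRT81 duplex cannot be told apart from an effect of KRT81 repression, because the design has 0 arrays of untransfected cells. Both may contribute, and neither the direction of cause nor the sequence of the duplexes was tested. Any other difference between the cultures, such as the plant extract in the description of the KRT81 siRNA sample, cannot be told apart either.

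The lower level of KRT83 is the next pattern. Its shared probe had a log2 ratio of -2.25, close to the -2.58 of KRT81, so KRT81 transcripts bound to that probe may account for its part of the difference. Binding of KRT81 transcripts to the probe listed for KRT83 alone is argued against as the whole cause, since its log2 ratio minus that of the KRT81 probe was -1.68, and it lay still further below the shared probe. Of 3148 genes with 2 measured probes, 46 (1.46%) had them at least that far apart. Compression of the very bright KRT81 signal was not tested, and silencing of KRT83 by the KRT81 siRNA and an effect of KRT81 repression on KRT83 both stay open.

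The last pattern is the set of single-spot probes that were bright on 1 array and not well above background on the other. Dim probes printed 10 times showed how often an isolated bright spot occurs, and the 95% limits below cover counting error only. With a signal above 300, such spots would give 21.0 probes (2.54 to 75.9) on the control siRNA array, where 38 were found, and 46.6 (12.7 to 119) on the KRT81 siRNA array, where 60 were found. With a signal above 100 the numbers were 210.1 (128 to 324) against 278 on the control siRNA array, and 222 (133 to 346) against 347 on the KRT81 siRNA array, the last just past its limit. Isolated bright spots may therefore account for many of these single-spot probes, although the numbers expected above 300 rest on 2 and 4 bright spots. Of the 1099 and 2401 probes well above background on 1 array only, those of lower signal were not covered. No biological explanation was tested for any of them.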
